A study of Mus musculus with 10 samples.

How the data were processed

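RNA-seq was performed on 10 libraries in 5 groups of 2, described by the submitters as biological replicates. HSPC and neutrophils were isolated with magnetic lineage depletion and neutrophil isolation kits, per the labels' protocols. RNA was depleted of ribosomal RNA and made into strand-specific libraries with a directional kit, per the labels' protocols. STAR 2.4.0, HTSeq and DiffBind and the mm10 genome are named per the submitters' processing notes, which do not say which step each served. Whether counting used the strand, which gene annotation was used, how reads mapping to several places were treated and which reads entered the RPKM denominator are not given in the sources used here.

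The authors deposited 1 table of RPKM values per library, in which reads per gene were divided by gene length and by a library total, so a library total that grows by reads outside the listed genes lowers every gene. Each table listed the same 16771 genes. Because a gene's RPKM values are whole multiples of what 1 read is worth, whole reads could be recovered: for each gene the smallest set of whole numbers with the observed ratios between libraries was found, within a tolerance of 0.02 reads, and the library totals were taken from the requirement that the implied gene length be a whole number of bases. This gave whole reads for 16655 of the 16655 genes above 0 in at least 2 libraries, and whole lengths for 100% of 2260 genes checked. Tested on simulated data for the same libraries (16554 genes), the recovery returned 99.8% of genes exactly. The recovered denominators were 55334692 and 57824373 reads for WT HSPC, 53914454 and 53754187 for Npm1c, 54899458 and 50227463 for Flt3-ITD, 44450779 and 48434887 for double mutant HSPC and 40783015 and 42986220 for neutrophils. Gene symbols were matched to GENCODE M21 on GRCm38, where 16158 of the symbols were found. A copy of a gene, an overlapping gene or a paralog can share reads, which cannot be checked here.

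Since RPKM values are not counts, tests were run with limma 3.58.1 (R 4.3.3) on log2(RPKM + 0.5), with an empirical Bayes variance trend, moderated statistics and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. Genes with at least 1 RPKM in at least 2 fitted libraries were tested, which left 9702 for the HSPC comparisons, fitted on 8 libraries, and 10174 for the neutrophil comparison, fitted on 10. A gene can pass that minimum through 1 group alone and then enters as a gene high in that group. The 7 comparisons made were each mutant group against WT HSPC, the double mutant against each single mutant, the interaction (double mutant minus both single mutants plus WT) and WT neutrophils against WT HSPC. The groups, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. P-values measure the spread between the replicates of this design. Values were tabulated with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 and drawn with matplotlib 3.10.9.

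Gene lists were tested with camera in limma, at a preset inter-gene correlation of 0.01, which compares a list with the other genes tested and so can point up while most of its members fall on the deposited scale. An estimated correlation was an alternative. The 26 lists, with the members found in the tables out of all members, were HoxA cluster (10 of 11), HoxB cluster (8 of 10), Hox partner factors (6 of 8), stem cell genes (20 of 20), myeloid and erythroid lineage regulators (22 of 22), primary granule genes (15 of 15), late neutrophil genes (24 of 24), monocyte and macrophage genes (22 of 22), dendritic cell genes (15 of 15), MHC class II genes (10 of 10), erythroid genes (26 of 30), megakaryocyte and platelet genes (19 of 19), mast cell, basophil and eosinophil genes (18 of 18), B cell genes (18 of 18), T and NK cell genes (19 of 20), stromal and endothelial genes (19 of 20), STAT5 and cytokine signalling targets (20 of 20), MAPK feedback genes (15 of 15), interferon response genes (29 of 30), immediate early and heat shock genes (21 of 21), S phase genes (25 of 25), G2 and mitosis genes (25 of 25), p53 target genes (20 of 20), nucleolar and MYC target genes (26 of 26), HSPC receptors and adhesion genes (24 of 24), mitochondrial transcripts (13 of 13). Lists with at least 3 tested members were tested, 24 in each comparison. Named genes were chosen by a rule fixed in advance. It took Npm1 and Flt3, and the 10 largest rises and the 10 largest falls with adjusted p under 0.05, at least 2 RPKM in the higher group and both libraries of one group above both of the other. It also took up to 3 members per list with the smallest adjusted p, and every measured Hox gene. Predicted and small RNA names and immunoglobulin and T cell receptor segments were left out of the ranking, and list members were named again where values are set side by side. The rule allowed 628 genes and comparisons, of which 167 are named. Some of the others are not reported here, and the rest were left out for length, a choice made after the alternatives had been run that favoured genes whose calls held under them. Genes named outside the rule are said to be so where they appear.

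The test was tried on simulated libraries with 200 changed genes. For the double mutant against WT (9025 genes) it called 12% of 1.2-fold, 86% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes, with 12 false calls among 161 (7.45%). For neutrophils against WT (9047 genes) it called 12%, 86%, 94% and 98%, with 11 false calls among 156 (7.05%). Replicates were checked against sampling noise on the recovered reads: the genes with at least 50 reads that differed beyond the 5% point made up 24.4% in WT HSPC, 33.9% in Npm1c, 53.9% in Flt3-ITD, 8.38% in the double mutant and 11.9% in neutrophils, so each pair differed by more than sampling noise. Over genes with at least 1000 reads, the coefficient of variation beyond sampling noise was estimated at 0.997% in the double mutant and 1.64% in neutrophils, against 3.08% in WT HSPC, 4.04% in Npm1c and 8.04% in Flt3-ITD. Repeat preparations of one sample are not excluded for those pairs, and p-values may then measure technical spread.

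Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter on low values, quantile normalization, median-of-ratios scaling, no variance trend, the replicate number as a block, all 10 libraries or the 4 WT libraries in the fit, leaving out each library, and the estimated correlation. Chosen after seeing the data were scaling to the reads on the listed genes, voom in limma on the recovered reads, library weights, a term for libraries with Y-linked expression, and correlations between comparisons without single libraries. Leaving out 1 library leaves its group with 1, whose spread is then taken from the other groups. Allele-specific expression, splicing and transcripts outside the listed genes were not analysed here.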

Results

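RNA was measured in 10 libraries from the bone marrow of C57BL/6 mice, in 5 groups of 2 biological replicates. In all, 4 of the groups were lineage-depleted haematopoietic stem and progenitor cells (HSPC), the immature fraction left after magnetic removal of cells with mature lineage markers. They came from wild-type (WT) mice, from mice with a floxed mutant Npm1 allele and the interferon-inducible Mx1-Cre recombinase (Npm1c), from mice with a knocked-in internal tandem duplication in 1 Flt3 allele (Flt3-ITD), and from mice with both (double mutant). The remaining group was WT neutrophils. NPM1 is a nucleolar chaperone whose mutant form is exported to the cytoplasm, FLT3 is a receptor tyrosine kinase of progenitors, and both are frequently mutated together in acute myeloid leukaemia.

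Values were deposited as RPKM, read numbers scaled by gene length and library total, for 16771 genes per library. The denominators, recovered from the values themselves, ran from 40783015 to 57824373 reads. The share on listed genes was 74.5% and 74.2% in WT HSPC, 60.9% and 63.1% in Npm1c, 69.5% and 63.5% in Flt3-ITD, 67.4% and 67.1% in double mutant HSPC, and 81.3% in both neutrophil libraries. The median log2 change of the tested genes was -0.26 in Npm1c, -0.14 in Flt3-ITD, -0.34 in the double mutant and -0.70 in neutrophils, each against WT HSPC. It was -0.09 and -0.18 for the double mutant against Npm1c and Flt3-ITD, and 0.09 for the interaction. Log2 changes below are therefore given relative to the median gene of their comparison, with the standard error of the fit and n = 2 libraries per group, while rose and fell refer to the test on the deposited scale. Levels are mean RPKM ± SD (n = 2). For gene lists, the number that rose and the number that fell when adjusted over the list alone follow the counts over all genes.

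**Figure D1:**
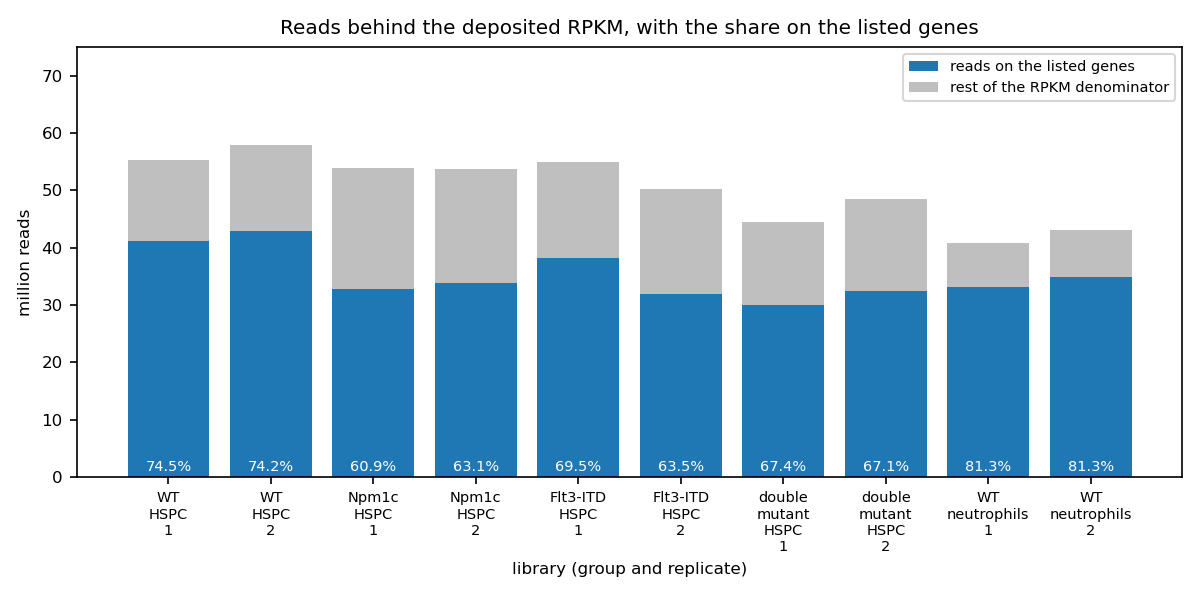
Reads per library in megareads (y axis) for the 10 libraries (x axis), split into reads on the listed genes and reads of the RPKM denominator that lay elsewhere. The share elsewhere averaged 25.7% in WT HSPC, 38.0% in Npm1c and 18.7% in neutrophils.

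Npm1 (chromosome 11, 33152287 to 33163206, GRCm38 with GENCODE M21) was expressed at 287 ± 3.72 RPKM in WT HSPC, 279.9 ± 21.3 in Npm1c, 284 ± 2.395 in Flt3-ITD, 144 ± 2.58 in the double mutant and 19.5 ± 0.690 in neutrophils. Flt3 (chromosome 5, 147330741 to 147400489) stood at 5.29 ± 0.0920, 3.40 ± 0.0622, 4.41 ± 0.993, 44.2 ± 0.0388 and 0.766 ± 0.0852 RPKM in the same order. Gene totals do not separate mutant from normal alleles, so neither gene checks the genotype labels. Relative to the median gene, Flt3 rose by 3.29 ± 0.12 in the double mutant (adjusted p = 1.06e-06), 9.76-fold on the log2(RPKM + 0.5) scale, and Npm1 changed by -0.65 ± 0.061 (adjusted p = 6.25e-06). In the single mutants Npm1 had values of 0.22 ± 0.061 in Npm1c (adjusted p = 0.621) and 0.13 ± 0.061 in Flt3-ITD (adjusted p = 0.895). Its log2 change on the deposited scale, -0.04 and -0.01, turned to 0.25 (adjusted p = 0.0160) and 0.16 under median-of-ratios scaling, 0.22 (adjusted p = 0.0199) and 0.15 under listed-gene scaling, 0.10 and 0.04 after quantile normalization, and 0.04 without Npm1c replicate 1 and 0.0008 without WT replicate 1. Flt3 fell in Npm1c (-0.31 ± 0.12, adjusted p = 0.00728). In Flt3-ITD its value was -0.11 ± 0.12 (adjusted p = 0.151), with adjusted p = 7.76e-04 without Flt3-ITD replicate 1 and 0.0485 with the Y-linked term.

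**Figure D2:**
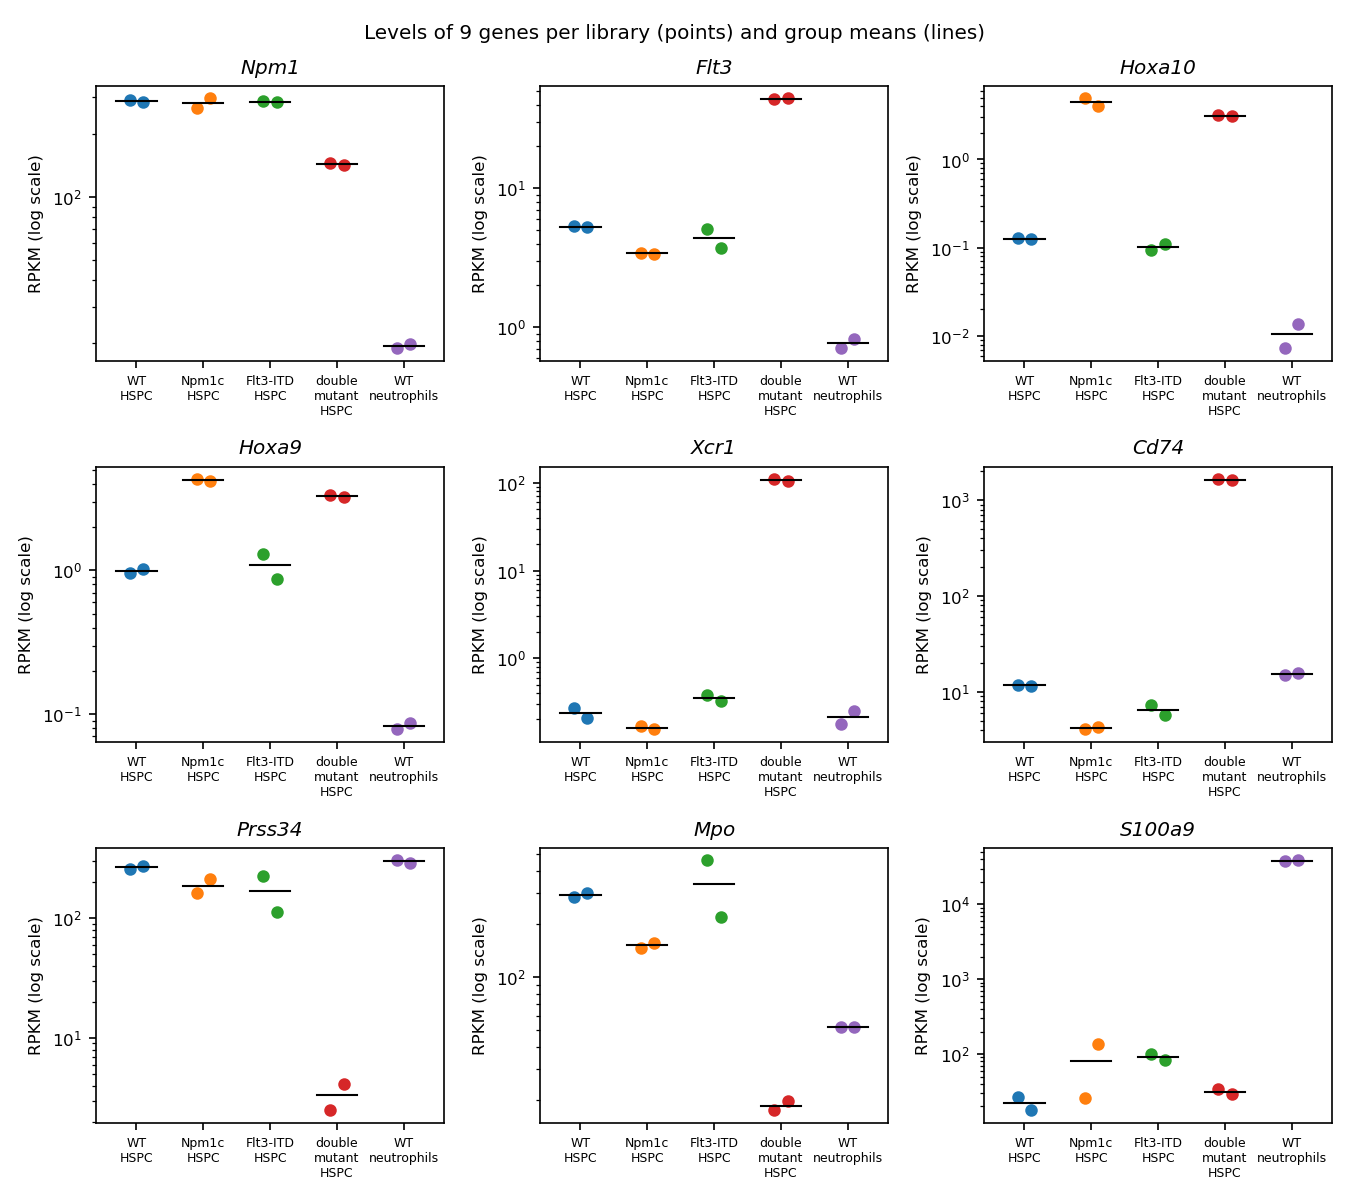
RPKM (y axis, log scale) of 9 genes in each of the 10 libraries (points) by group (x axis), with lines at the group means. Hoxa10 averaged 4.48 RPKM in Npm1c and 0.127 in WT HSPC, and Cd74 reached 1646 in the double mutant.

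The Npm1c against WT comparison asked what the mutant nucleophosmin alone did to HSPC transcription. Genes of the HoxA cluster, transcription factors of stem and early progenitor cells, rose together: Hoxa10 (chromosome 6, 52231197 to 52240854) went from 0.127 ± 0.00210 to 4.48 ± 0.608 RPKM, with a log2 change of 3.24 ± 0.085 (adjusted p = 2.22e-05). Relative to the median gene and on the log2(RPKM + 0.5) scale this is 9.47-fold. Hoxa9 (chromosome 6, 52223100 to 52231089) rose by 1.93 ± 0.12, Hoxa6 by 1.42 ± 0.14, Hoxa5 by 1.34 ± 0.18 and Hoxa7 by 0.96 ± 0.13. All 5 tested HoxA genes rose (5 and 0 adjusted over the list alone). The HoxA list had a camera adjusted p = 3.57e-16, and adjusted p = 0.152 with an estimated correlation. No HoxB gene reached the expression minimum, so 0 members of that list were tested. Hox partner genes had too few tested members for a list test, and among them Pbx2 fell (-0.22 ± 0.074). Sfrp4, a secreted Wnt modulator, rose by 1.69 ± 0.12, Pde3b, a cyclic nucleotide phosphodiesterase, by 1.49 ± 0.19 and Efcab7 by 1.42 ± 0.13.

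Transcripts of the mitochondrial genome were also higher, and 12 of 13 rose (13 and 0 adjusted over the list alone), led by mt-Atp8 (1.40 ± 0.18), mt-Cytb (1.11 ± 0.091) and mt-Co2 (0.96 ± 0.10). For the mitochondrial list, camera gave adjusted p = 6.90e-27, and adjusted p = 0.156 with an estimated correlation. Of the p53 target genes, 6 of 16 rose, 5 fell and 5 did not pass (6 and 5 adjusted over the list alone). The p53 target list had a camera adjusted p = 4.50e-06, and adjusted p = 0.487 with an estimated correlation. The p53 members that rose included Phlda3 (1.31 ± 0.16) and Ccng1 (0.94 ± 0.095), while Trp53inp1 fell (-0.36 ± 0.051); 8 rose and 1 fell under median-of-ratios scaling. Among immediate early and heat shock genes, which respond within minutes to handling and stress, 5 of 20 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone), with Egr1 at 0.84 ± 0.12 and the chaperone gene Hsph1 at 0.70 ± 0.085. For the immediate early list, camera gave adjusted p = 1.97e-09, and adjusted p = 0.487 with an estimated correlation. Late neutrophil genes lay above the median gene (list median 0.97), although 3 of 20 rose, 2 fell and 15 did not pass (0 and 0 adjusted over the list alone). The late neutrophil list had a camera adjusted p = 3.78e-12, and adjusted p = 0.503 with an estimated correlation. The granule gene Ngp was at 23.8 and 106 RPKM in the Npm1c libraries, and its rise of 2.25 ± 0.58 (adjusted p = 0.0227) was lost without WT replicate 1 (adjusted p = 0.0758) or 2 (adjusted p = 0.103) and with no filter (adjusted p = 0.0541).

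Proliferation genes fell. All 25 G2 and mitosis genes fell (0 and 25 adjusted over the list alone), and 0 rose and 21 fell under median-of-ratios scaling. For the G2 and mitosis list, camera gave adjusted p = 1.72e-07, and adjusted p = 0.678 with an estimated correlation. Mki67, the Ki-67 antigen of cycling cells, dropped from 122 ± 8.23 to 35.1 ± 2.395 RPKM (-1.52 ± 0.13, adjusted p = 4.14e-04), and the spindle genes Bub1b and Hmmr changed by -0.50 ± 0.046 and -0.49 ± 0.049. Of the S phase genes, 0 of 25 rose, 22 fell and 3 did not pass (0 and 22 adjusted over the list alone), and 2 rose and 13 fell under median-of-ratios scaling; the replication factor gene Cdc45 changed by -0.41 ± 0.047 and Uhrf1 by -0.56 ± 0.069. The S phase list had a camera adjusted p = 1.64e-04, and adjusted p = 0.760 with an estimated correlation. The largest fall among genes of the naming rule was that of the histone gene Hist1h4m (-3.95 ± 0.094), followed by Phyhip (-1.86 ± 0.089) and Acp5 (-1.74 ± 0.069).

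Several myeloid and lineage genes fell singly, in lists that did not pass the list test on the deposited scale. For the myeloid and erythroid lineage regulators, 0 of 20 rose, 14 fell and 6 did not pass (camera adjusted p = 0.182), including Irf8, a regulator of monocyte and dendritic cell fate (-0.91 ± 0.13). In the monocyte and macrophage list, 0 of 22 rose, 16 fell and 6 did not pass (camera adjusted p = 0.121), with Ccr2 at -0.98 ± 0.079 and Mpeg1 at -0.88 ± 0.12. MHC class II genes gave 0 rises and 9 falls in 10 (camera adjusted p = 0.252), with Cd74, the invariant chain, at -1.13 ± 0.097. Interferon response genes gave 1 rise and 19 falls in 27 (camera adjusted p = 0.219), with Isg15 at -0.94 ± 0.12. For erythroid genes, 1 of 25 rose, 16 fell and 8 did not pass (camera adjusted p = 0.333), with Sptb at -0.96 ± 0.055. For megakaryocyte and platelet genes, 0 of 19 rose, 13 fell and 6 did not pass (camera adjusted p = 0.380), with Thbs1 at -1.06 ± 0.15. Adjusted over the list alone, the falls numbered 17, 17, 9, 21, 16 and 14 in that order, and under median-of-ratios scaling 9, 12, 4, 14, 10 and 5. These lists passed downward under other settings. The monocyte list did so under median-of-ratios, quantile and listed-gene scaling, with no filter, and with the replicate block (adjusted p = 6.67e-05, 3.67e-05, 2.50e-04, 0.00500 and 0.0455) and the interferon list without Npm1c replicate 1, under median-of-ratios, quantile and listed-gene scaling, and with no filter (adjusted p = 0.00832, 0.00321, 0.00847, 0.00619 and 0.0123). The MHC class II list and the lineage regulators passed under median-of-ratios, quantile and listed-gene scaling and with no filter (adjusted p = 0.0158, 0.0125, 0.0191 and 0.0451, and 0.0352, 0.00657, 0.0481 and 0.00746). Erythroid genes passed without Npm1c replicate 2, under quantile scaling, and with no filter (adjusted p = 0.0223, 0.00657 and 0.0117) and platelet genes without Npm1c replicate 1 and under median-of-ratios and quantile scaling (adjusted p = 1.13e-08, 0.0304 and 0.00847). Of the nucleolar and MYC target genes, 0 of 26 rose, 10 fell and 16 did not pass on the deposited scale, but 9 rose and 3 fell under median-of-ratios scaling (camera adjusted p = 0.375). That list passed upward under median-of-ratios and listed-gene scaling (adjusted p = 0.0181 and 0.0191). The STAT5 list passed the list test upward (camera adjusted p = 0.0159, and adjusted p = 0.738 with an estimated correlation), although 3 of its genes rose and 8 fell and 6 of 18 met the expression minimum through the double mutant alone; 5 rose and 4 fell under median-of-ratios scaling. The call was lost without Npm1c replicate 1, under median-of-ratios, quantile and listed-gene scaling, and with no filter (adjusted p = 0.0935, 0.554, 0.550, 0.482 and 0.278). The medians and means of the primary granule, mast cell, B cell and stromal lists were negative while their list test pointed up, without passing; it pointed down under quantile, median-of-ratios and listed-gene scaling, where primary granule genes passed after quantile normalization (adjusted p = 0.0124). The B cell list passed upward with no filter (adjusted p = 3.15e-05), when 2 of 18 rose and 3 fell.

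In all, 5880 of 9702 genes passed in limma, 242 higher and 5638 lower (95.9% lower). That split was set by the scaling: it was 1708 higher and 2008 lower under median-of-ratios scaling (54.0% lower), 1865 and 1613 after quantile normalization (46.4%) and 1476 and 2258 scaled to the listed genes (60.5%). Past the threshold, 35 genes lay at least 2-fold above the median gene and 33 at least 2-fold below it. There were 136 higher and 3271 lower without WT replicate 1, 101 and 3322 without WT replicate 2, 183 and 3547 without Npm1c replicate 1 and 133 and 4380 without Npm1c replicate 2.

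The Flt3-ITD against WT comparison asked the same of the activated receptor alone. The negative feedback gene Socs2, a target of STAT5 downstream of FLT3, went from 0.0407 ± 0.00946 to 0.822 ± 0.358 RPKM (1.41 ± 0.16, adjusted p = 0.00380). In the STAT5 list, 4 of 18 rose, 1 fell and 13 did not pass (4 and 1 adjusted over the list alone). Camera gave adjusted p = 1.91e-05, and 0.391 with an estimated correlation. With no filter 2 of 20 rose and 1 fell. The MAPK feedback genes, read out of another arm of receptor signalling, moved both ways: 2 of 10 rose, 3 fell and 5 did not pass (camera adjusted p = 0.971), with Spry4 at -0.81 ± 0.080, Etv5 at -0.81 ± 0.095 and Ccnd1, a G1 cyclin, at -1.009 ± 0.11. None of the 5 HoxA genes passed in limma (camera adjusted p = 0.112, smallest adjusted p = 0.627, for Hoxa10), and none had an unadjusted p under 0.05. The list passed upward without Flt3-ITD replicate 2 (adjusted p = 0.0326).

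Some heat shock and interferon genes rose. Hspa1b, an inducible HSP70 gene, rose by 2.14 ± 0.29 and Xaf1 by 1.16 ± 0.12. Of the immediate early and heat shock genes, 8 of 20 rose, 0 fell and 12 did not pass (8 and 0 adjusted over the list alone), and of the interferon response genes 8 of 27 rose, 1 fell and 18 did not pass (8 and 1 adjusted over the list alone). For the immediate early and interferon lists, camera gave adjusted p = 3.07e-11 and 5.12e-13, and adjusted p = 0.391 for each with an estimated correlation. Mitochondrial transcripts gave 4 rises in 13 (8 and 0 adjusted over the list alone). For the mitochondrial list, camera gave adjusted p = 3.07e-11, and adjusted p = 0.391 with an estimated correlation. Late neutrophil genes had the largest list median (1.29), and 7 of 20 rose (11 and 0 adjusted over the list alone). Camera gave adjusted p = 5.12e-13, and 0.391 with an estimated correlation. With no filter 2 of 24 rose. Ngp, at 13.5 and 11.1 RPKM in WT HSPC, stood at 75.1 and 70.0 in Flt3-ITD HSPC (2.65 ± 0.58), and its call was lost without WT replicate 1 (adjusted p = 0.0872), without WT replicate 2 (adjusted p = 0.105) and with library weights (adjusted p = 0.0686). In the monocyte and macrophage list, 3 of 22 rose, 0 fell and 19 did not pass (1 and 0 adjusted over the list alone). For the monocyte list, camera gave adjusted p = 2.71e-09, and adjusted p = 0.391 with an estimated correlation.

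Mitotic, erythroid and platelet genes fell. Mki67 changed by -1.58 ± 0.13 (adjusted p = 0.00152), the kinesin gene Cenpe by -0.82 ± 0.090 and Hmmr by -0.38 ± 0.049. Of the G2 and mitosis genes, 19 of 25 fell (0 and 23 adjusted over the list alone). The G2 and mitosis list had a camera adjusted p = 3.18e-06, and adjusted p = 0.608 with an estimated correlation. The erythroid list had 17 falls in 25 (0 and 19 adjusted over the list alone), led by the spectrin gene Sptb (-0.71 ± 0.055), the water channel gene Aqp1 (-0.52 ± 0.061) and the ankyrin gene Ank1 (-0.57 ± 0.071). For the erythroid list, camera gave adjusted p = 3.05e-04, and adjusted p = 0.608 with an estimated correlation. The erythroid and megakaryocyte regulators Gata1 and Zfpm1 changed by -0.43 ± 0.056 and -0.50 ± 0.046, and platelet genes gave 15 falls in 19 (0 and 19 adjusted over the list alone), including Selp (-1.13 ± 0.18) and Gp5 (-0.46 ± 0.087). The platelet list had a camera adjusted p = 3.36e-04, and adjusted p = 0.608 with an estimated correlation. Under median-of-ratios scaling the falls in these lists numbered 11, 7 and 6. The erythroid call was lost without Flt3-ITD replicate 1 (adjusted p = 0.355), and the platelet call without Flt3-ITD replicate 1 (adjusted p = 0.170). Hist1h4m (-3.82 ± 0.094), the high-affinity IgE receptor gene Fcer1a (-1.34 ± 0.17), the plasma cell genes Mzb1 (-1.57 ± 0.16) and Tnfrsf17 (-1.20 ± 0.18) and the collagen gene Col1a2 (-1.26 ± 0.16) were among the larger falls.

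The remaining lists depended on the scaling or on single libraries. Stem cell genes (8 of 10 fell, 0 rose) lost the call without WT replicate 2 or Flt3-ITD replicate 1 and with the Y-linked term (adjusted p = 0.0601, 0.271 and 0.145). For the stem cell list, camera gave adjusted p = 0.0192, and adjusted p = 0.608 with an estimated correlation. S phase genes (13 of 25 fell) lost it without Flt3-ITD replicate 1 and under median-of-ratios, quantile and listed-gene scaling (adjusted p = 0.0918, 0.222, 0.110 and 0.165). The S phase list had a camera adjusted p = 0.0211, and adjusted p = 0.735 with an estimated correlation. Nucleolar genes (14 of 26 fell) lost it without Flt3-ITD replicate 1 and under median-of-ratios and listed-gene scaling (adjusted p = 0.403, 0.0623 and 0.0529). For the nucleolar list, camera gave adjusted p = 0.00393, and adjusted p = 0.608 with an estimated correlation. The primary granule list passed upward with 0 single genes past the threshold in 14. The primary granule list had a camera adjusted p = 0.00326, and adjusted p = 0.608 with an estimated correlation. It turned downward without Flt3-ITD replicate 1 (adjusted p = 0.0108), and Mpo stood at 457 and 219.8 RPKM in those libraries. The call was lost under median-of-ratios, quantile and listed-gene scaling and with the Y-linked term (adjusted p = 0.222, 0.296, 0.174 and 0.149). Dendritic cell genes (2 rose and 2 fell of 12) lost the call without WT replicate 2 or Flt3-ITD replicate 1 or 2, under median-of-ratios, quantile and listed-gene scaling, and with no filter (adjusted p = 0.0508, 0.0663, 0.0781, 0.360, 0.537, 0.324 and 0.207). For the dendritic cell list, camera gave adjusted p = 0.0229, and adjusted p = 0.572 with an estimated correlation. MHC class II genes (0 rose and 1 fell of 10) lost it without WT replicate 2 or Flt3-ITD replicate 1, under median-of-ratios, quantile and listed-gene scaling, with no filter, and with the Y-linked term (adjusted p = 0.0572, 0.403, 0.307, 0.308, 0.276, 0.155 and 0.149). The MHC class II list had a camera adjusted p = 0.0325, and adjusted p = 0.608 with an estimated correlation. Through the double mutant libraries alone passed the minimum 6 of 18 STAT5, 9 of 22 monocyte, 5 of 12 dendritic and 6 of 27 interferon genes. Adjusted over the list alone, the falls were 8, 18 and 18 for stem cell, S phase and nucleolar genes.

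Of 9702 genes, 3213 passed in limma, 180 higher and 3033 lower (94.4% lower), against 786 higher and 952 lower under median-of-ratios scaling (54.8%), 722 and 976 after quantile normalization (57.5%) and 711 and 1073 scaled to the listed genes (60.1%). At least 2-fold from the median gene lay 31 higher and 15 lower genes. The Flt3-ITD replicates stood further apart than those of any other group, with 53.9% of genes differing beyond the 5% point of sampling noise, and both the count and the split moved with single libraries. There were 26 higher and 456 lower without WT replicate 1, 32 and 625 without WT replicate 2, 216 and 5450 without Flt3-ITD replicate 1, 1044 and 2784 without Flt3-ITD replicate 2 (72.7% lower) and 54 and 1106 with library weights.

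The double mutant against WT comparison asked what both mutations did together. Antigen presentation and dendritic cell genes rose from low levels. H2-Eb1 (chromosome 17, 34305867 to 34316674), an MHC class II chain, went from 3.91 ± 0.546 to 2184 ± 6.46 RPKM (9.30 ± 0.23, adjusted p = 1.32e-07), and Cd74 (chromosome 18, 60803848 to 60812652) from 11.7 ± 0.191 to 1646 ± 1.95 (7.41 ± 0.097). H2-Aa rose by 9.21 ± 0.20, H2-Ab1 by 8.29 ± 0.12 and Ciita, the transactivator of this gene family, by 7.16 ± 0.076. All 10 MHC class II genes rose (10 and 0 adjusted over the list alone). For the MHC class II list, camera gave adjusted p = 8.37e-10, and adjusted p = 0.351 with an estimated correlation. The chemokine receptor gene Xcr1 (chromosome 9, 123852315 to 123862029) of conventional type 1 dendritic cells rose by 7.53 ± 0.067, the integrin gene Itgax (CD11c) by 6.06 ± 0.066 and Naaa by 7.43 ± 0.15, and all 12 dendritic cell genes rose (12 and 0 adjusted over the list alone). The dendritic cell list had a camera adjusted p = 1.75e-10, and adjusted p = 0.196 with an estimated correlation. Plbd1, at 8.01 ± 0.21, and the survival genes Bcl2a1d (7.45 ± 0.11) and Bcl2a1a (7.42 ± 0.078), near-identical paralogs whose reads are hard to assign, were among the 10 largest rises.

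Of the monocyte and macrophage genes, 18 of 22 rose, 1 fell and 3 did not pass (18 and 1 adjusted over the list alone), with examples in the perforin-like gene Mpeg1 (5.05 ± 0.12) and the complement gene C1qc (4.08 ± 0.087). For the monocyte list, camera gave adjusted p = 7.61e-09, and adjusted p = 0.398 with an estimated correlation. Interferon response genes gave 26 rises in 27 (26 and 0 adjusted over the list alone), among them the antiviral GTPase gene Mx1 (3.02 ± 0.056) and the transcription factor gene Irf7 (3.19 ± 0.079). The interferon list had a camera adjusted p = 7.28e-13, and adjusted p = 0.351 with an estimated correlation. The T and NK cell list passed the list test at the preset correlation in every comparison. That call is not read as a direction. All 6 tested of its 19 genes (5 of 7 for neutrophils) passed the expression minimum through the double mutant libraries alone. With no filter 16 of 19 rose and 0 fell here; Cd8a, which type 1 dendritic cells also express, was at 2.85 ± 0.054. Immediate early and heat shock genes, a list fixed as a sign of cell handling, rose in 16 of 20 and fell in 3 (16 and 3 adjusted over the list alone), led by Nr4a1 (4.28 ± 0.060) and Atf3 (4.27 ± 0.074). For the immediate early list, camera gave adjusted p = 2.44e-08, and adjusted p = 0.398 with an estimated correlation. STAT5 targets gave 10 rises and 4 falls in 18 (10 and 4 adjusted over the list alone), with Bcl6 at 3.95 ± 0.095, Cish at 2.08 ± 0.058 and Pim1 at 2.19 ± 0.090. The STAT5 list had a camera adjusted p = 9.39e-04, and adjusted p = 0.554 with an estimated correlation. The p53 target list rose in 8 of 16 and fell in 5 (8 and 5 adjusted over the list alone), led by the apoptosis gene Pmaip1 (5.85 ± 0.13), and its call was lost without double mutant replicate 1 or 2 and under median-of-ratios scaling (adjusted p = 0.0679, 0.0661 and 0.0561). For the p53 target list, camera gave adjusted p = 0.0184, and adjusted p = 0.632 with an estimated correlation. HSPC receptor genes gave 13 rises and 4 falls in 23 (13 and 4 adjusted over the list alone), including Csf2ra (2.88 ± 0.20). The receptor list had a camera adjusted p = 6.77e-04, and adjusted p = 0.632 with an estimated correlation. Tested members that passed the minimum through the double mutant libraries alone, and so entered as genes high there, were 2 of 10 MHC class II, 5 of 12 dendritic, 9 of 22 monocyte, 6 of 27 interferon, 4 of 20 immediate early, 6 of 18 STAT5, 4 of 16 p53 target, 1 of 23 receptor and 1 of 5 HoxA genes. With no filter 10 of 10, 14 of 15, 17 of 22, 26 of 29, 17 of 21, 12 of 20, 7 of 20, 14 of 24 and 9 of 10 rose in that order.

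The HoxA rise seen in Npm1c was present: all 5 tested genes rose (5 and 0 adjusted over the list alone), with Hoxa10 at 2.87 ± 0.085, Hoxa5 at 2.12 ± 0.18 and Hoxa9 at 1.68 ± 0.12. For the HoxA list, camera gave adjusted p = 4.31e-04, and adjusted p = 0.389 with an estimated correlation. Pbx2, a HOX cofactor gene, fell (-0.36 ± 0.074). Of the stem cell genes, 3 of 10 rose, 6 fell and 1 did not pass (camera adjusted p = 0.974), Sult1a1 rising by 2.89 ± 0.081 and Pdzk1ip1 falling (-1.19 ± 0.067). MAPK feedback genes had a median of -0.36 and a mean of 0.61, and 3 of 10 rose, 6 fell and 1 did not pass (camera adjusted p = 0.604), with Ccnd1 at 2.96 ± 0.11 and Dusp5 at 3.49 ± 0.12.

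Basophil, mast cell and megakaryocytic genes fell. The basophil protease gene Prss34 (chromosome 17, 25298394 to 25300165) went from 267 ± 8.25 to 3.32 ± 1.17 RPKM (-5.83 ± 0.34, adjusted p = 3.68e-06), Mcpt8 changed by -5.47 ± 0.39, the eosinophil granule gene Prg2 by -4.58 ± 0.47 and the mast cell carboxypeptidase gene Cpa3 by -3.93 ± 0.33. In that list 1 of 13 rose, 12 fell and 0 did not pass (1 and 12 adjusted over the list alone), a call lost with voom on the recovered reads (adjusted p = 0.130). The mast cell list had a camera adjusted p = 0.0228, and adjusted p = 0.715 with an estimated correlation. Mpo (chromosome 11, 87793581 to 87804413), myeloperoxidase of primary granules, went from 291 ± 8.54 to 18.7 ± 1.505 RPKM (-3.59 ± 0.29) and Elane changed by -3.31 ± 0.40, and 13 of 14 primary granule genes fell (camera adjusted p = 0.103). That list passed downward under median-of-ratios, quantile and listed-gene scaling and with no filter (adjusted p = 0.00691, 0.0497, 0.0465 and 0.0424). The platelet tubulin gene Tubb1 changed by -3.73 ± 0.20 and Gp5 by -2.04 ± 0.087, and of the platelet genes 1 of 19 rose, 18 fell and 0 did not pass (1 and 18 adjusted over the list alone). For the platelet list, camera gave adjusted p = 0.00417, and adjusted p = 0.744 with an estimated correlation. Erythroid genes fell in 19 of 25 and rose in 4 (4 and 19 adjusted over the list alone), with Gata1 at -1.20 ± 0.056, Epor at -1.26 ± 0.064 and Hemgn at -1.09 ± 0.050; the call was lost without double mutant replicate 1 or 2 (adjusted p = 0.0622 and 0.0660). The erythroid list had a camera adjusted p = 0.0350, and adjusted p = 0.744 with an estimated correlation. The progenitor regulators Myb and Gfi1b changed by -2.11 ± 0.097 and -2.05 ± 0.071, in a list where 4 of 20 rose, 12 fell and 4 did not pass (camera adjusted p = 0.604).

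Cell cycle and ribosome biogenesis genes fell: 25 of 25 S phase genes (0 and 25 adjusted over the list alone), such as Rrm1 (-1.04 ± 0.052) and Cdc6 (-1.10 ± 0.054). For the S phase list, camera gave adjusted p = 3.67e-05, and adjusted p = 0.632 with an estimated correlation. So did 24 of 25 G2 and mitosis genes (0 and 24 adjusted over the list alone), such as Bub1b (-1.012 ± 0.046), and 26 of 26 nucleolar and MYC target genes (0 and 26 adjusted over the list alone), such as Polr1b (-1.02 ± 0.071) and Nop56 (-0.69 ± 0.046). For the G2 and mitosis and nucleolar lists, camera gave adjusted p = 6.71e-05 and 2.07e-04, and adjusted p = 0.632 for each with an estimated correlation. Under median-of-ratios scaling 21 nucleolar genes fell and 0 rose. Late neutrophil genes gave 3 rises and 2 falls in 20 (2 and 2 adjusted over the list alone), a call lost under median-of-ratios, quantile and listed-gene scaling and with no filter (adjusted p = 0.311, 0.118, 0.0698 and 0.0755). For the late neutrophil list, camera gave adjusted p = 0.02501, and adjusted p = 0.744 with an estimated correlation. Of the B cell genes 1 of 6 rose, 2 fell and 3 did not pass, with median 0.33, mean -0.12 and a list test pointing up (camera adjusted p = 0.650) that passed with no filter (adjusted p = 0.0154), when 8 of 18 rose and 2 fell. Stromal and endothelial genes gave 1 rise and 5 falls in 6 (camera adjusted p = 0.584), and mitochondrial transcripts 4 rises and 2 falls in 13 (camera adjusted p = 0.105), a list that passed upward without double mutant replicate 1 (adjusted p = 0.0160).

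The test called 8035 of 9702 genes, 2316 higher and 5719 lower (71.2% lower), against 3748 higher and 3715 lower under median-of-ratios scaling (49.8%). There were 3737 higher and 7036 lower with no filter, and 1390 and 5197 without double mutant replicate 1 (78.9%) and 1415 and 5186 without replicate 2 (78.6%), when fewer genes passed the minimum. Beyond 2-fold from the median gene the balance was the opposite, 1519 higher and 393 lower, and beyond 8-fold it was 294 and 18.

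**Figure D3:**
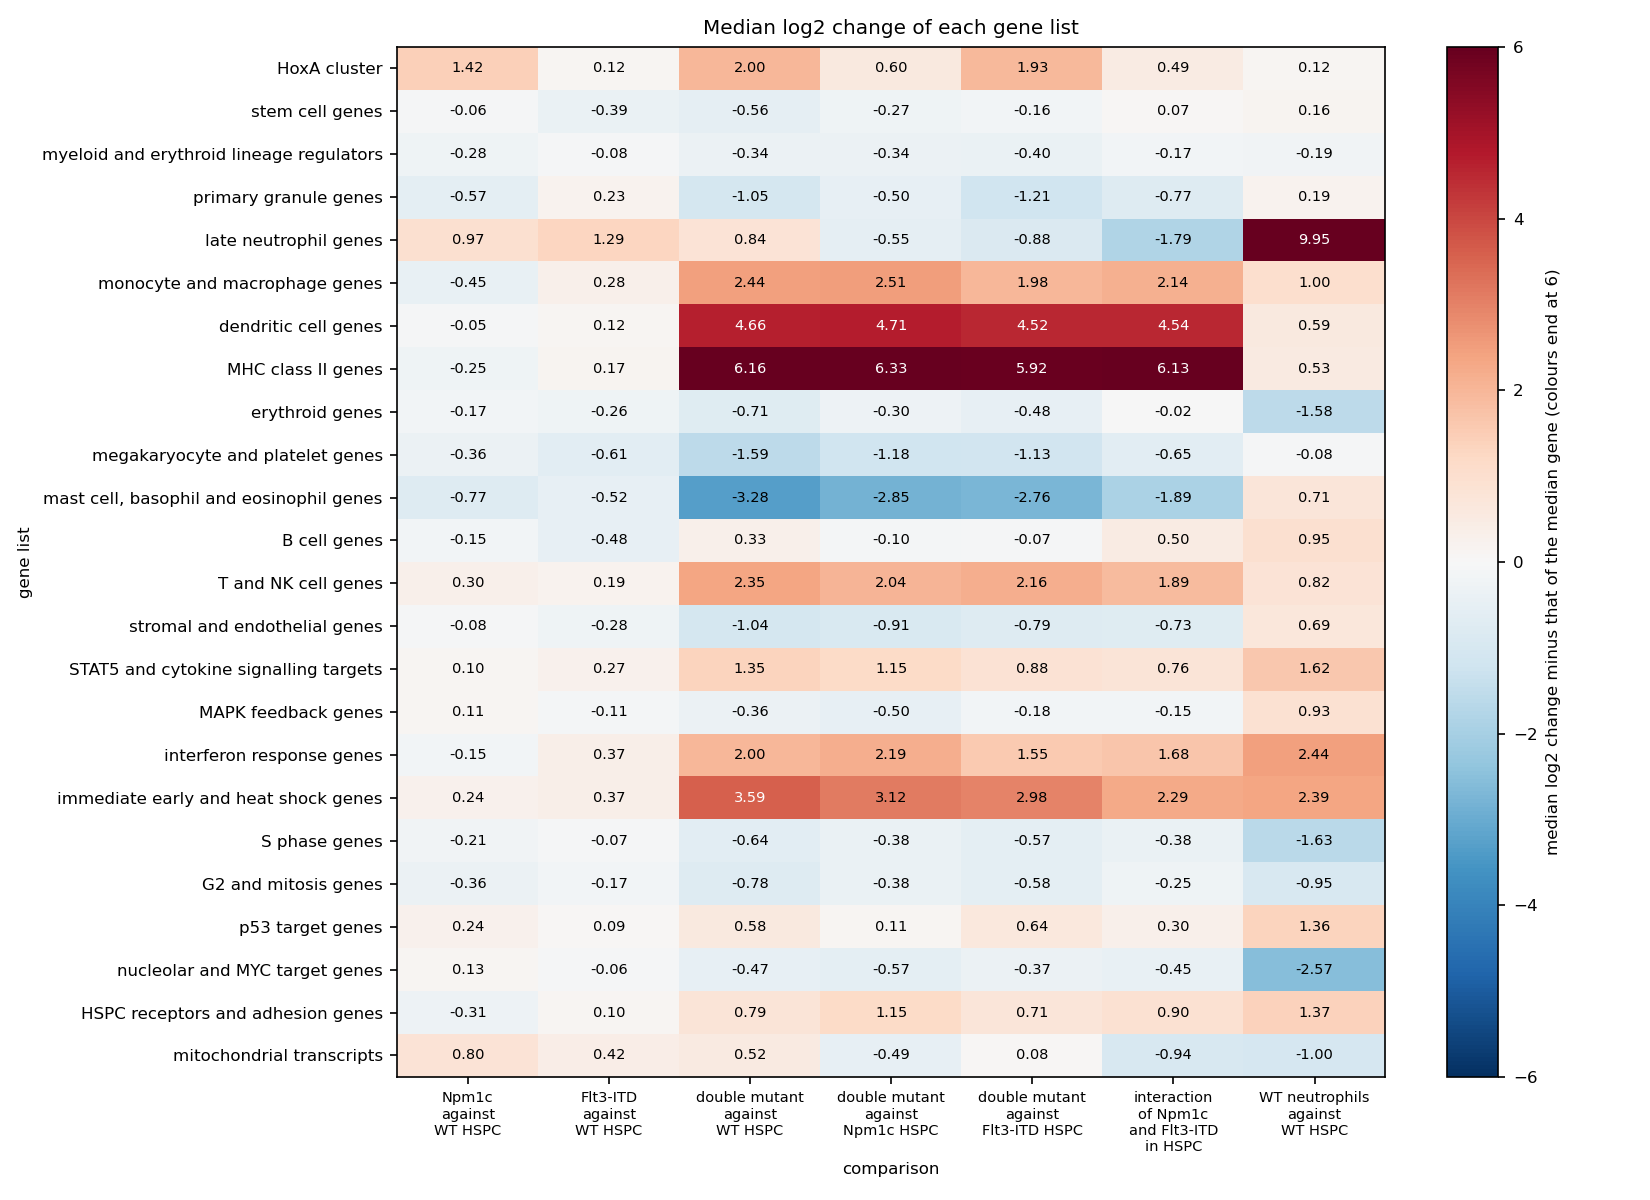
Median log2 change relative to the median gene (colour, ending at 6 on either side) of 24 gene lists (rows) in 7 comparisons (columns). The MHC class II median was 6.16 in the double mutant against WT and -0.25 in Npm1c, and the late neutrophil median was 9.95 in neutrophils.

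Across the 7 comparisons the list tests above used a preset inter-gene correlation of 0.01. With the correlation estimated from the replicates, 0 of 24 lists passed in camera in any comparison, the unadjusted p was under 0.05 for 3 lists in Npm1c, 1 in Flt3-ITD, 3 in the double mutant against WT and 0 in neutrophils, and the smallest adjusted p was 0.152, in Npm1c.

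The double mutant was then compared with Npm1c HSPC, which lack the Flt3-ITD allele. Cd74 rose from 4.18 ± 0.165 to 1646 ± 1.95 RPKM (8.55 ± 0.097, adjusted p = 5.06e-09), H2-Eb1 by 10.10 ± 0.23, Xcr1 by 7.45 ± 0.067, Flt3 by 3.61 ± 0.12 and the creatine kinase gene Ckb by 7.22 ± 0.078. All 10 MHC class II genes (10 and 0 adjusted over the list alone), all 12 dendritic cell genes (12 and 0 adjusted over the list alone) and all 27 interferon response genes (27 and 0 adjusted over the list alone) rose. For the MHC class II, dendritic cell and interferon lists, camera gave adjusted p = 3.29e-07, 1.59e-07 and 4.78e-10, and adjusted p = 0.546, 0.392 and 0.501 with an estimated correlation. The monocyte list rose in 19 of 22 and fell in 1 (19 and 1 adjusted over the list alone), with Irf8 (chromosome 8, 120736358 to 120756694) up by 4.02 ± 0.13. For the monocyte list, camera gave adjusted p = 3.29e-07, and adjusted p = 0.697 with an estimated correlation. Immediate early genes gave 15 rises and 2 falls in 20 (16 and 2 adjusted over the list alone), and receptor genes 17 and 3 in 23 (17 and 3 adjusted over the list alone). For the immediate early and receptor lists, camera gave adjusted p = 9.45e-05 and 0.00128, and adjusted p = 0.697 for each with an estimated correlation. STAT5 targets rose in 11 of 18 and fell in 3 (12 and 3 adjusted over the list alone), with Pim1 at 2.71 ± 0.090, a call lost without double mutant replicate 1 or 2 (adjusted p = 0.0886 and 0.0800). For the STAT5 list, camera gave adjusted p = 0.00749, and adjusted p = 0.697 with an estimated correlation. Ccnd1, lower in each single mutant, rose by 3.77 ± 0.11.

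Among HoxA genes Hoxa7 was higher (0.91 ± 0.13) and Hoxa10 lower (-0.36 ± 0.085). Of those tested 3 of 5 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.689), and with no filter 7 of 10 rose and 1 fell. Prss34 changed by -5.56 ± 0.34, Cpa3 by -4.08 ± 0.33 and Mpo by -2.90 ± 0.29. The mast cell list fell in 12 of 13 (1 and 12 adjusted over the list alone) and the platelet list in 17 of 19 (1 and 17 adjusted over the list alone). For the mast cell and platelet lists, camera gave adjusted p = 0.00270 and 0.00120, and adjusted p = 0.697 for each with an estimated correlation. The S phase list fell in 25 of 25 (0 and 25 adjusted over the list alone), the G2 and mitosis list in 21 of 25 (2 and 21 adjusted over the list alone), and the nucleolar list in 23 of 26 (0 and 23 adjusted over the list alone). For the S phase, G2 and mitosis and nucleolar lists, camera gave adjusted p = 2.16e-05, 0.00128 and 1.44e-05, and adjusted p = 0.697 for each with an estimated correlation. Mitochondrial transcripts, high in Npm1c, fell in 9 of 13 (0 and 9 adjusted over the list alone), with mt-Nd3 at -1.51 ± 0.14; that call was lost without Npm1c replicate 1 or double mutant replicate 1 and under median-of-ratios, quantile and listed-gene scaling (adjusted p = 0.0642, 0.0641, 0.0517, 0.339 and 0.0818). The mitochondrial list had a camera adjusted p = 0.0273, and adjusted p = 0.697 with an estimated correlation. In limma 7508 genes passed, 3336 higher and 4172 lower, against 4974 and 4962 with no filter, 3895 and 3865 under median-of-ratios scaling and 2903 and 5308 after quantile normalization, with 1628 and 365 at least 2-fold from the median gene.

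The comparison with Flt3-ITD HSPC, which lack mutant Npm1, followed. The HoxA genes rose here, 5 of 5 (5 and 0 adjusted over the list alone), with Hoxa10 at 2.78 ± 0.085 and Hoxa9 at 1.45 ± 0.12. For the HoxA list, camera gave adjusted p = 0.00195, and adjusted p = 0.512 with an estimated correlation. Cd74 went from 6.47 ± 1.08 to 1646 ± 1.95 RPKM (8.07 ± 0.097, adjusted p = 6.98e-09), H2-Ab1 rose by 8.13 ± 0.12, Xcr1 by 7.16 ± 0.067, Batf3, a transcription factor gene of type 1 dendritic cells, by 3.93 ± 0.054 and Flt3 by 3.38 ± 0.12. All 10 MHC class II genes (10 and 0 adjusted over the list alone) and all 12 dendritic cell genes (12 and 0 adjusted over the list alone) rose, as did 24 of 27 interferon genes (24 and 0 adjusted over the list alone). For the MHC class II, dendritic cell and interferon lists, camera gave adjusted p = 2.47e-08, 7.89e-09 and 4.69e-09, and adjusted p = 0.442, 0.282 and 0.442 with an estimated correlation. The monocyte list had 16 rises and 3 falls in 22 (17 and 3 adjusted over the list alone), immediate early genes 16 and 3 in 20 (16 and 3 adjusted over the list alone), and receptor genes 13 and 5 in 23 (13 and 5 adjusted over the list alone), among them Cd9 (2.21 ± 0.12). For the monocyte, immediate early and receptor lists, camera gave adjusted p = 5.37e-06, 5.37e-06 and 0.00881, and adjusted p = 0.636, 0.636 and 0.709 with an estimated correlation. STAT5 targets (10 rose and 4 fell of 18, 10 and 5 adjusted over the list alone) lost the call without double mutant replicate 1 or 2 (adjusted p = 0.170 and 0.167), and p53 targets (10 and 4 of 16, 10 and 4 adjusted over the list alone) without Flt3-ITD replicate 1 (adjusted p = 0.0522). For the STAT5 and p53 target lists, camera gave adjusted p = 0.0118 and 0.0118, and adjusted p = 0.636 for each with an estimated correlation.

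Mpo fell from 338 ± 168 to 18.7 ± 1.505 RPKM (-3.87 ± 0.29), Elane changed by -3.56 ± 0.40, Prss34 by -5.25 ± 0.34 and the hedgehog receptor gene Smo by -3.28 ± 0.061. Falls covered 13 of 14 primary granule genes (0 and 13 adjusted over the list alone), 12 of 13 mast cell genes (1 and 12 adjusted over the list alone) and 16 of 19 platelet genes (1 and 17 adjusted over the list alone). For the primary granule, mast cell and platelet lists, camera gave adjusted p = 0.0165, 0.00683 and 0.00683, and adjusted p = 0.709, 0.636 and 0.709 with an estimated correlation. Npm1 itself was lower by 0.80 ± 0.061, within a nucleolar list that fell in 22 of 26 (0 and 22 adjusted over the list alone). The nucleolar list had a camera adjusted p = 2.49e-04, and adjusted p = 0.636 with an estimated correlation. S phase genes fell in 25 of 25 (0 and 25 adjusted over the list alone) and G2 and mitosis genes in 21 of 25 (2 and 21 adjusted over the list alone). For the S phase and G2 and mitosis lists, camera gave adjusted p = 4.85e-06 and 3.43e-04, and adjusted p = 0.636 for each with an estimated correlation. In total 7514 genes passed in limma, 2778 higher and 4736 lower (63.0% lower), against 3811 higher and 3717 lower under median-of-ratios scaling (49.4%), with 1439 and 330 at least 2-fold from the median gene. There were 4299 higher and 5657 lower with no filter, 1756 and 4120 without double mutant replicate 1 and 1780 and 4117 without replicate 2.

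The interaction tests whether the double mutant departed from the sum of the single-mutant changes on the log2 scale, the question of synergy. Cd74 lay 9.19 ± 0.14 above that sum (adjusted p = 5.01e-08), H2-Eb1 9.76 ± 0.32, Xcr1 7.05 ± 0.095, the activation marker gene Cd83 6.89 ± 0.15, Ccnd1 4.74 ± 0.16 and Flt3 3.68 ± 0.17. All 12 dendritic cell, 10 MHC class II and 27 interferon genes were higher than the sum. Camera gave adjusted p = 9.51e-07, 1.51e-06 and 4.17e-07, and 0.566, 0.611 and 0.611 with an estimated correlation. With no filter 14 of 15, 10 of 10 and 28 of 29 were higher. Through the double mutant alone 5, 2 and 6 of the tested genes, and 9 of 22 monocyte genes, met the minimum. The monocyte list was higher in 19 and lower in 1 of 22, with Irf8 at 3.55 ± 0.18, the immediate early list in 16 and 3 of 20, and receptor genes in 15 and 3 of 23. For these lists camera gave adjusted p = 6.81e-05, 0.00394 and 0.0255, and 0.732, 0.808 and 0.812 with an estimated correlation. Adjusted over each list alone, the 6 higher counts were the same. Mki67 stood 2.64 ± 0.18 above the sum, being low in each single mutant and at 70.9 ± 1.75 RPKM in the double mutant.

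Prss34 lay below the sum at -5.01 ± 0.48, Cpa3 at -3.55 ± 0.46, Ngp at -3.72 ± 0.82, Mpo at -3.20 ± 0.41 and Npm1 at -1.03 ± 0.087. Lower than the sum were 10 of 13 mast cell genes (1 and 11 adjusted over the list alone) and 18 of 26 nucleolar genes with 3 higher (3 and 19 adjusted over the list alone). For these lists camera gave adjusted p = 6.43e-04 and 1.92e-04, and 0.732 for each with an estimated correlation. So were 14 of 25 S phase genes (0 and 14 adjusted over the list alone) and 10 of 13 mitochondrial transcripts (0 and 10 adjusted over the list alone), with mt-Nd3 at -2.08 ± 0.20. For these lists camera gave adjusted p = 1.81e-04 and 3.21e-04, and 0.808 and 0.732 with an estimated correlation. Primary granule genes (6 of 14) lost the call under quantile and listed-gene scaling and with the Y-linked term (adjusted p = 0.151, 0.0762 and 0.105), and the mitochondrial transcripts under quantile scaling (adjusted p = 0.0878). The primary granule list had a camera adjusted p = 0.0182, and 0.812 with an estimated correlation. Late neutrophil genes (11 lower and 3 higher of 20) lost it without Flt3-ITD replicate 1 or double mutant replicate 2, under median-of-ratios, quantile and listed-gene scaling, and with the Y-linked term (adjusted p = 0.0570, 0.0599, 0.0567, 0.295, 0.257 and 0.156). For the late neutrophil list, camera gave adjusted p = 0.0236, and 0.815 with an estimated correlation. Platelet genes (9 and 1 of 19) lost it without Npm1c replicate 1 and under quantile and listed-gene scaling (adjusted p = 0.0987, 0.102 and 0.0884). The platelet list had a camera adjusted p = 0.0112, and 0.812 with an estimated correlation. For HoxA genes 3 were higher and 1 lower of 5 (camera adjusted p = 0.966), and with no filter 5 and 1 of 10, with Hoxa7 at 0.67 ± 0.19.

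Of 9702 genes, 6480 departed from the sum in limma, 3800 higher and 2680 lower (41.4% lower). The split turned to 2802 higher and 4790 lower after quantile normalization (63.1%) and 3023 and 4296 when scaled to the listed genes (58.7%). At least 2-fold from the median gene were 1599 higher and 478 lower genes.

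**Figure D4:**
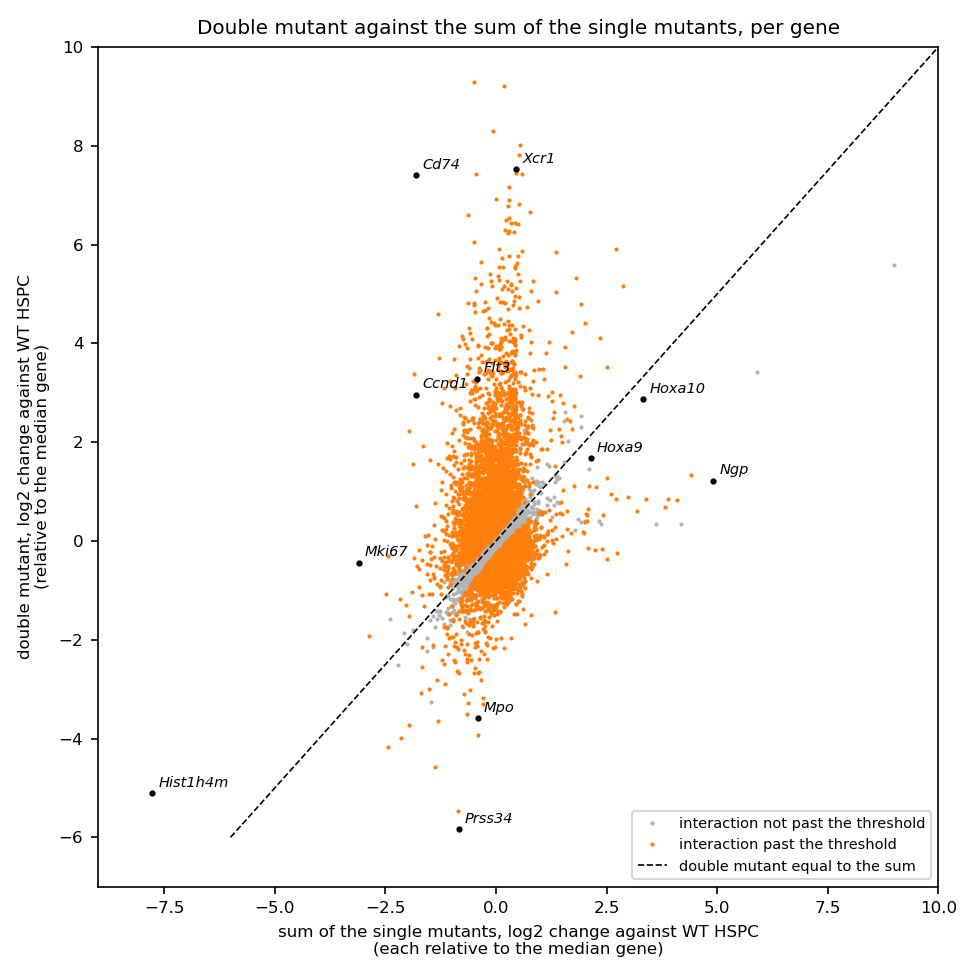
Log2 change of the double mutant against WT (y axis) against the sum of the log2 changes of Npm1c and Flt3-ITD (x axis) for 9702 genes (points), each relative to its median gene, with genes whose interaction passed in orange and the dashed line where both are equal. Cd74 lies above the line and Prss34 and Mpo below it.

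WT neutrophils against WT HSPC gave the pattern of normal granulocytic maturation. S100a9 (chromosome 3, 90692632 to 90695721), a calcium-binding alarmin, went from 22.2 ± 6.27 to 38274 ± 484 RPKM (11.45 ± 0.61, adjusted p = 2.73e-07), Retnlg rose by 11.40 ± 0.66, Ngp by 11.04 ± 0.54, the lactoferrin gene Ltf by 10.87 ± 0.49 and the collagenase gene Mmp8 by 10.56 ± 0.51. All 24 late neutrophil genes rose (24 and 0 adjusted over the list alone). For the late neutrophil list, camera gave adjusted p = 5.17e-12, and adjusted p = 0.789 with an estimated correlation. Interferon response genes rose in 23 of 29 and fell in 4 (23 and 4 adjusted over the list alone), with Ifit3 at 5.94 ± 0.076, and immediate early genes in 13 and 5 of 20 (13 and 5 adjusted over the list alone). For the interferon and immediate early lists, camera gave adjusted p = 1.27e-07 and 0.00172, and adjusted p = 0.789 for each with an estimated correlation. STAT5 targets gave 11 rises and 5 falls in 18 (11 and 5 adjusted over the list alone), with Socs3 at 4.58 ± 0.072. For the STAT5 list, camera gave adjusted p = 0.00423, and adjusted p = 0.789 with an estimated correlation. The immediate early call was lost under median-of-ratios scaling (adjusted p = 0.0673), and the STAT5 call under median-of-ratios scaling (adjusted p = 0.139). Of the p53 target genes 9 of 17 rose, 8 fell and 0 did not pass (camera adjusted p = 0.0661), with Fas at 5.46 ± 0.088, and the list passed upward without neutrophil replicate 1 (adjusted p = 0.0436). Primary granule genes, made in earlier promyelocytes, split with 5 of 15 rose, 5 fell and 5 did not pass (camera adjusted p = 0.306).

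The stem and progenitor marker genes Cd34 and Kit changed by -3.36 ± 0.19 and -1.97 ± 0.070, Npm1 by -3.15 ± 0.059, the spermidine synthase gene Srm by -3.18 ± 0.057, Gnl3 by -3.15 ± 0.057 and Myc by -2.45 ± 0.073. Falls covered 25 of 26 nucleolar genes (0 and 25 adjusted over the list alone) and all 25 S phase genes (0 and 25 adjusted over the list alone). For the nucleolar and S phase lists, camera gave adjusted p = 5.63e-05 and 1.08e-04, and adjusted p = 0.789 for each with an estimated correlation. They also covered all 25 G2 and mitosis genes (0 and 25 adjusted over the list alone) and 19 of 25 erythroid genes (0 and 19 adjusted over the list alone). For the G2 and mitosis and erythroid lists, camera gave adjusted p = 9.22e-04 and 0.0265, and adjusted p = 0.789 for each with an estimated correlation. Under median-of-ratios scaling 18 erythroid genes fell and 6 rose. All 13 mitochondrial transcripts fell (0 and 13 adjusted over the list alone), a call lost without neutrophil replicate 2 and under listed-gene scaling (adjusted p = 0.0558 and 0.0855). The mitochondrial list had a camera adjusted p = 0.0391, and adjusted p = 0.789 with an estimated correlation. The 5 HoxA genes fell on the deposited scale, but their median relative to the median gene was 0.12 and their mean -0.06 (camera adjusted p = 0.498). Monocyte genes (10 rose and 7 fell of 22) lost the call under median-of-ratios and quantile scaling, with no filter, and with the 4 WT libraries alone (adjusted p = 0.323, 0.189, 0.0649 and 0.0862). For the monocyte list, camera gave adjusted p = 0.0391, and adjusted p = 0.806 with an estimated correlation. Receptor genes (13 rose and 11 fell of 24) lost it without WT replicate 1 or 2, under median-of-ratios and quantile scaling, and with no filter (adjusted p = 0.0527, 0.0506, 0.255, 0.189 and 0.0854). The receptor list had a camera adjusted p = 0.0481, and adjusted p = 0.827 with an estimated correlation.

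In limma 9283 of 10174 genes passed, 2892 higher and 6391 lower (68.8% lower), against 4632 higher and 4544 lower under median-of-ratios scaling (49.5%) and 3867 and 5361 after quantile normalization (58.1%).

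How far the comparisons resembled each other was measured over 9702 genes, which are not independent replicates. All of them share the WT HSPC libraries, so unchanged groups simulated against those libraries correlate too, and the simulated value of 100 draws is given beside each. The double mutant and Npm1c changes had r = 0.0536 (simulated 0.495) and a covariance of 0.0180 (simulated 0.00485). Under median-of-ratios scaling that r turned negative, to -0.0420, and it was -0.0019 with a pseudocount of 0.1 and -0.0033 and -0.0013 without double mutant replicates 1 and 2. For the double mutant and Flt3-ITD, r was 0.363 (simulated 0.499) and the covariance 0.0976 (simulated 0.00488), and for Npm1c and Flt3-ITD 0.531 (0.495) and 0.0393 (0.00484). That last r was 0.674 without replicate 1 and 0.310 without replicate 2, and its SD over single libraries was 0.207. The double mutant and the sum of the single mutants had r = 0.218 (simulated 0.575) and a covariance of 0.116 (simulated 0.00974), and the double mutant and neutrophils 0.480 (0.496) and 0.851 (0.00486).

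Genes higher in both the double mutant and Npm1c numbered 84, where independent lists of the same lengths would share 57.8, and genes lower in both 3432 (independent 3323). For the double mutant and Flt3-ITD the numbers were 94 (43.0) and 2338 (1788), for Npm1c and Flt3-ITD 68 (4.49) and 2676 (1763), and for the double mutant and neutrophils 1295 (579.8) and 4856 (3767). These counts are on the deposited scale and carry its split toward lower, which moved with the scaling. Among genes at least 2-fold from the median gene in both comparisons, the shared higher and lower genes numbered 19 (5.48) and 16 (1.34) for the double mutant and Npm1c, 15 (4.85) and 12 (0.608) for the double mutant and Flt3-ITD, 10 (0.112) and 5 (0.0510) for the single mutants and 865 (369) and 186 (78.0) for the double mutant and neutrophils. Simulated groups held no change, so set no baseline. With 2 WT libraries the controls could not be split into pairs, so part of the excess may come from sharing them.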

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

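The interaction test was fixed in advance, and the tests that weigh the denominator and abundant genes were chosen after the results were seen. The interaction drew attention because the test of the difference itself passed for 6480 genes, 3800 higher and 2680 lower in the double mutant than the sum of the single mutants, a balance that turned to 2802 and 4790 after quantile normalization and 3023 and 4296 scaled to the listed genes. The share of the RPKM denominator that lay outside the listed genes, which no comparison uses, was above both WT HSPC libraries in every mutant HSPC library. It averaged 38.0% (SD 1.54) in Npm1c, 33.5% (SD 4.25) in Flt3-ITD and 32.7% (SD 0.269) in the double mutant, against 25.7% (SD 0.225) in WT HSPC.

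Most genes called in the single mutants were lower than in WT, and a candidate explanation, reads of the denominator outside the listed genes, cannot be told apart from other causes. Scaled to the reads on the listed genes, 60.5% of called genes were lower in Npm1c and 60.1% in Flt3-ITD, and between Flt3-ITD replicates 2 and 1 the median gene shifted by -0.12 on the log2 scale, where the ratio of their shares on listed genes gives -0.13; both follow from dividing each library by 1 factor and test no cause. A few abundant listed genes taking the reads are excluded, since the 10 highest genes gained 0.474 and 0.333 percentage points where the loss of the median gene would need 16.5 and 9.41, while abundant RNAs outside the listed genes were not measured. Open and untested is whether the genotype changed how much RNA falls outside the listed genes, or whether RNA depletion differed between the preparations.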

How the results depend on the processing

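The settings added after the data were seen were scaling to the listed genes, voom, library weights, the Y-linked term and r without single libraries; the tests under all other settings were chosen in advance. Outside the settings named here, each count of changed genes stayed within 1.5 times its value. For Npm1c it was 3478 after quantile normalization, 3716 under median-of-ratios scaling and 3734 scaled to the listed genes, and for Flt3-ITD 1698, 1738 and 1784, and 1160 with library weights. Leaving out 1 library gave 3407 (WT replicate 1) to 4513 (Npm1c replicate 2) genes for Npm1c and 482 (WT replicate 1) to 5666 (Flt3-ITD replicate 1) for Flt3-ITD. The other ranges were 6587 to 7259 for the double mutant, 5830 to 6907 against Npm1c, 5876 to 7923 against Flt3-ITD, 4827 to 7264 for the interaction and 8592 to 8978 for neutrophils. Replicate numbers did not pair the samples (r from -0.111 to 0.107 over 10 pairs of groups), and with the replicate block the counts were 5529, 2630, 7931, 7349, 7379, 6273 and 9270 in the order of the report. Lists past the threshold numbered 0 in all 7 comparisons with an estimated correlation. They numbered 14 in Npm1c with no filter and 14 with quantile normalization (9 as reported), 10 in Flt3-ITD under median-of-ratios and 10 under listed-gene scaling (16 as reported), and 7 in neutrophils under median-of-ratios scaling (12 as reported). Without single libraries the lists numbered 9 to 11 for Npm1c, 11 to 16 for Flt3-ITD, 14 to 17 for the double mutant, 11 to 15 for the double mutant against Npm1c, 14 to 16 for the double mutant against Flt3-ITD, 12 to 14 for the interaction and 10 to 13 for neutrophils. The r of the double mutant with Npm1c (0.0536) was -0.0019 and 0.0768 with pseudocounts 0.1 and 1, 0.0972 with no filter, 0.0013 with quantile normalization and -0.0420 under median-of-ratios scaling. With Flt3-ITD r was 0.280 with quantile normalization, with the sum 0.143 with quantile normalization and 0.124 under median-of-ratios scaling, and with neutrophils 0.466 and 0.484 with pseudocounts 0.1 and 1, 0.449 with no filter, 0.443 with quantile normalization and 0.439 under median-of-ratios scaling. Without single libraries r ran from -0.0033 to 0.0621 for the double mutant with Npm1c, 0.265 to 0.384 with Flt3-ITD, 0.163 to 0.264 with the sum and 0.474 to 0.483 with neutrophils, and from 0.310 to 0.674 for the single mutants. Of 2806 values of the 175 named genes and comparisons under all settings, 2789 kept direction and side of the threshold, 6 lost the call, 2 gained it and 9 turned direction. These genes were favoured for holding, and of 10200 values of all 628 genes and comparisons the naming rule allowed, 9797 did so, 332 lost the call, 37 gained it and 34 turned. Npm1 in Npm1c turned to 0.0968 (quantile normalization), 0.253 (median-of-ratios scaling), 0.225 (listed-gene scaling), and Npm1 in Flt3-ITD turned to 0.0371 (quantile normalization), 0.163 (median-of-ratios scaling), 0.148 (listed-gene scaling), and Hoxa10 in Flt3-ITD turned to 0.0119 (term for Y-linked expression). Without single libraries Npm1 ran from -0.114 to 0.0412 in Npm1c and from -0.0256 to 0.0008 in Flt3-ITD. The cause was not tested, except that scaling to the listed genes, quantile normalization and median-of-ratios scaling move the median gene by construction. With 2 libraries per group, 12% of simulated 1.2-fold changes were called. Limits for low genes or wide spread stay open.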

Other observations

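In this part the tests were chosen after the result was seen, apart from those on single-exon copies and on position near Npm1 or Flt3, and the subtype gene lists and the genes named here were chosen after values were seen. In the double mutant all 16 genes of the conventional type 1 dendritic cell list rose against WT HSPC (16 under median-of-ratios scaling), including the dead-cell receptor gene Clec9a, from 1.19 ± 0.0873 to 50.7 ± 0.772 RPKM (5.26 ± 0.20), the endosomal RNA sensor gene Tlr3 (6.43 ± 0.063), the integrin gene Itgae (CD103), from 0.290 ± 0.0632 to 74.3 ± 0.152 RPKM (6.90 ± 0.076), and the cross-presentation gene Wdfy4 (4.65 ± 0.16). All 12 genes of the activated dendritic cell list rose, with a list median of 4.71 and each passing the expression minimum through the double mutant libraries alone, among them the homing receptor gene Ccr7 (6.65 ± 0.11), Fscn1 (5.27 ± 0.064), the costimulatory gene Cd86 (5.90 ± 0.068) and the chemokine gene Ccl22 (5.64 ± 0.077). Of the conventional type 2 list, 8 of 10 tested genes rose with a median of 1.39, and of the plasmacytoid list 4 of 6 with a median of 1.83. Through the double mutant libraries alone passed 10 of 16 type 1, 2 of 10 type 2 and 3 of 6 plasmacytoid genes, and with no filter 16 of 16, 11 of 14, 7 of 12 and, of the activated list, 12 of 12 rose, with medians of 4.96, 0.73, 0.74 and 4.43. In Npm1c alone 0 type 1 genes rose and 6 of 16 fell, and in Flt3-ITD alone 2 rose and 2 fell.

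The dendritic and MHC class II rise may come from cells with the pattern of conventional type 1 dendritic cells in the double mutant preparation or from progenitors that express these genes, and bulk RNA does not separate the possibilities, so the genotype as a biological source stays open. The type 1 list rose by a median of 5.24, and H2-Eb1 and Cd74 reached 2184 ± 6.46 and 1646 ± 1.95 RPKM. Of the 16 type 1 genes, 6 were at 1 RPKM or more in WT HSPC and 7 stand in other lists. Lineage depletion removes cells with the kit's lineage markers, which sources used here do not list. The erythroid median lay 2.57 above the mast cell median against WT (1.32 to 3.42, resampling genes, not libraries). The gap was 2.55 (0.94 to 3.56) against Npm1c and 2.28 (0.996 to 3.24) against Flt3-ITD. At 5 RPKM or more in WT HSPC (23 and 10 genes) it was 3.01 (1.58 to 3.99). For these genes it argues against dilution of otherwise unchanged HSPC by cells expressing neither list. With no filter, adding low genes, the gap was 1.83 (-0.807 to 3.08). The dendritic median lay above that of B cell genes by 4.33 (2.397 to 7.52) and of late neutrophil genes by 3.82 (2.03 to 5.86). With no filter the gaps were 2.74 (1.04 to 5.62) and 2.53 (0.926 to 5.50). The gaps restate the rise, so a lower share of HSPC is not excluded.

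Copies of other genes differed several-fold between replicates, and a candidate explanation is sequence variants of single-exon copies carried by some mice, which stays open. Gm8730 (chromosome 8, 102864845 to 102865798), a processed pseudogene of the ribosomal gene Rplp0, had 6.76 and 7.15 RPKM in WT HSPC, 351 and 365 in Npm1c, 10.04 and 344 in Flt3-ITD, and 287 and 277 in the double mutant, and an effect of the Npm1c allele cannot be told apart. The Flt3-ITD libraries, which lack the allele, lay 0.50 and 5.53 log2 above the WT mean, so 1 library alone speaks against it, while all 4 libraries with the allele were high. Of 6 placed genes off the Y chromosome that differed over 8-fold between replicates, 33.3% had a single exon, against 2.36% of 12052 genes with as many reads, but those are the copies that drew attention, so the share restates the pattern, and 0 of the other 4 had a single exon. Segments linked to the targeted alleles cannot be told apart, with 16.7% of those 6 genes within 10 Mb of Npm1 or Flt3, and neither can reads assigned to a copy in place of its parent, since the coefficient of variation was 15.6% for Rplp0 and Gm8730 summed and 23.4% for Rplp0 alone, but 18.3% for Rpl15 and its copy Gm10020 summed and 18.4% for Rpl15 alone.

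The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty averaged 3.14 RPKM in Npm1c replicate 2 and 3.35 in Flt3-ITD replicate 1, and at most 0.00203 in each other library. These groups may thus each hold mice of both sexes, which the labels do not give, and with the Y-linked term 6826 genes passed in Npm1c and 4437 in Flt3-ITD.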
